A study of Mus musculus with 6 samples.

How the data were processed

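RNA sequencing had been run on total RNA of mouse retina, 3 normal and 3 OIR samples, all at postnatal day 17. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit, which in its standard form does not mark the strand. The deposited table holds raw counts per gene for the 6 libraries, with the gene length, position and biotype beside them as other columns; gene length was not used. Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the mm10 genome build. The annotation release, the strand setting and the filters on reads are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene cannot be told apart without strand, and genes with near-identical copies (the globin genes, C4b, the gamma crystallins, and Acta2 with the other smooth and skeletal muscle actins) are uncertain. Of the 54532 gene IDs, 99.9% matched the GENCODE vM21 annotation of mm10, and 98.3% of those had the same start and end. Of the symbols, 27 had been altered to dates, and their names were taken from the reference by gene ID. Where a symbol had several IDs, the one with the most counts was used.

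Columns were matched to samples by the names in the table: OIR columns by the group, day and number in the titles, and the other columns at the same day, which carry no OIR, to the normal samples with that number. Depth was 15818168 to 17163513 counts per library. The counts of every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 7.20 to 23.1 over genes with at least 40 counts in the pair), so all were kept as separate samples.

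The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; glmQLFit and glmQLFTest) on the deposited counts with TMM scaling, genes kept by filterByExpr (minimum count 10, total 15), all 6 libraries and no covariate, with Benjamini-Hochberg adjustment over the 17108 genes kept and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.131. CPM values, computed here from the deposited counts, are scaled with the TMM factors, and means are given with the SD over 3 libraries. Where the normal libraries held 0 counts, a fold is a lower bound against 3 counts over the group, and where they held 1 to 3 counts the ratio of summed counts is given with a 95% Clopper-Pearson interval, which covers counting error only. The 30 gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with estimated correlations and with fry, over the 29 lists with at least 4 tested genes; 15 genes stand in 2 lists. The lists covered hypoxia, endothelial-to-mesenchymal transition, extracellular matrix, fibronectin receptors, tip cells, reactive glia, inflammation, complement, cell cycle, sterol synthesis and immediate early genes, and markers of endothelial, mural, Müller, astrocyte, microglial, rod, cone, bipolar, amacrine, horizontal, ganglion, pigment epithelial, lens, stromal, corneal, muscle, oligodendrocyte and erythroid cells and of sex.

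Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took 8 genes by name (Fn1, Vegfa, Acta2, Tagln, Cdh5, Pecam1, Gfap, Itga5), the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM, groups that do not overlap and a symbol that is no clone name or pseudogene, and per list up to 4 members with the smallest adjusted p or, where fewer than 2 passed, the highest mean CPM. Fap, Cdh2, Snai1, Snai2, Twist1, Zeb1, Zeb2, Fbn1, Kdr, Tek, Npy and Arc were named after their values were seen.

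Alternatives were DESeq2 1.42.0 and limma-voom, median-of-ratios size factors, library totals alone, no filter, a stricter filter (at least 1 CPM in 3 libraries), the replicate number as a block, leaving out each library, and a threshold of 0.01. A fit with the sex of each library, read from Xist and Y-linked genes, as a covariate and a fit without the lens genes were added after seeing the data. The tests were checked on simulated counts with the means, dispersions and library sizes of the OIR against normal comparison, of which 16841 genes passed the filter. The 200 changed genes were drawn from those with a mean of at least 1 CPM, so the rates do not cover genes with lower counts. They are also a smaller share than the 19.8% of genes called in the data. EdgeR recovered 26%, 74%, 94% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, and 9 of its 156 calls were false. DESeq2 recovered 38%, 74%, 94% and 98% with 13 false of 165 calls, and limma-voom 28%, 74%, 94% and 100% with 10 false of 158 calls. Camera called the list of 15 genes raised by at least 1 on the log2 scale and 0 of 50 lists of unchanged genes, which were drawn without correlation between genes.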

Results

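Messenger RNA levels were measured by RNA sequencing in whole retina of wild-type C57BL/6J mice at postnatal day 17. One group of 3 samples came from normal mice and one group of 3 from mice with OIR, the usual abbreviation of oxygen-induced retinopathy, a model in which pups are kept in high oxygen and then returned to room air, after which the retina becomes hypoxic and grows abnormal vessels. The oxygen schedule is not given in the sources used here. The series sets out to find a target linked to hypoxia-driven retinal vessel growth, and its title names fibronectin and the transition of endothelial cells to mesenchymal cells. The deposited table gave counts for 54532 genes, with 15818168 to 17163513 counts per library, and 17108 genes had enough counts to be tested. The genes left out held 0.164% of all counts. Normal and OIR libraries lay apart on the first principal component, which held 54.9% of the variance. By Xist and Y-linked transcripts, 2 normal libraries and 1 OIR library came from males, and 1 normal library and 2 OIR libraries from females. Each group thus held libraries of both sexes and so of at least 2 animals, but the labels do not say whether all libraries came from separate animals, so p-values measure only the spread between these samples.

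Fibronectin mRNA was higher in every OIR library than in every normal library. Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200, minus strand, mm10), which encodes the matrix glycoprotein that integrins bind, had 112 ± 9.96 CPM (counts per 1e6 counts, TMM-scaled) in normal retina and 496 ± 49.4 CPM in OIR retina (SD, n = 3 per group). Its log2 fold change was 2.14 with a standard error of 0.093, or 4.41-fold, with an adjusted p of 4.25e-07 in edgeR's quasi-likelihood test. The difference was 2.36 on the log2 scale among male libraries and 1.92 among female libraries. An exact two-sided permutation test of the mean log2 CPM gave p = 0.1, the smallest that 3 samples against 3 allow. Itga5, the alpha subunit of the main fibronectin receptor, rose 4.25-fold, from 5.84 ± 1.10 to 24.9 ± 3.34 CPM (SD, n = 3). Vegfa, the hypoxia-induced endothelial growth factor, rose 3.11-fold, from 137 ± 12.6 to 426 ± 22.6 CPM. The endothelial junction genes Cdh5 and Pecam1 rose 2.70-fold and 2.19-fold, with adjusted p of 0.000117 and 2.89e-05 in the edgeR test. Gfap, an intermediate filament of astrocytes and stressed Müller glia, rose 11.8-fold, from 22.1 ± 1.98 to 261 ± 44.2 CPM. Among the smooth muscle genes, Acta2 rose 7.42-fold, from 6.42 ± 1.44 to 47.8 ± 14.4 CPM (edgeR adjusted p of 1.9e-05), whereas Tagln was close to the detection limit, with 29 counts in the 3 normal libraries and 23 in the 3 OIR libraries, and was not tested.

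**Figure D1:**
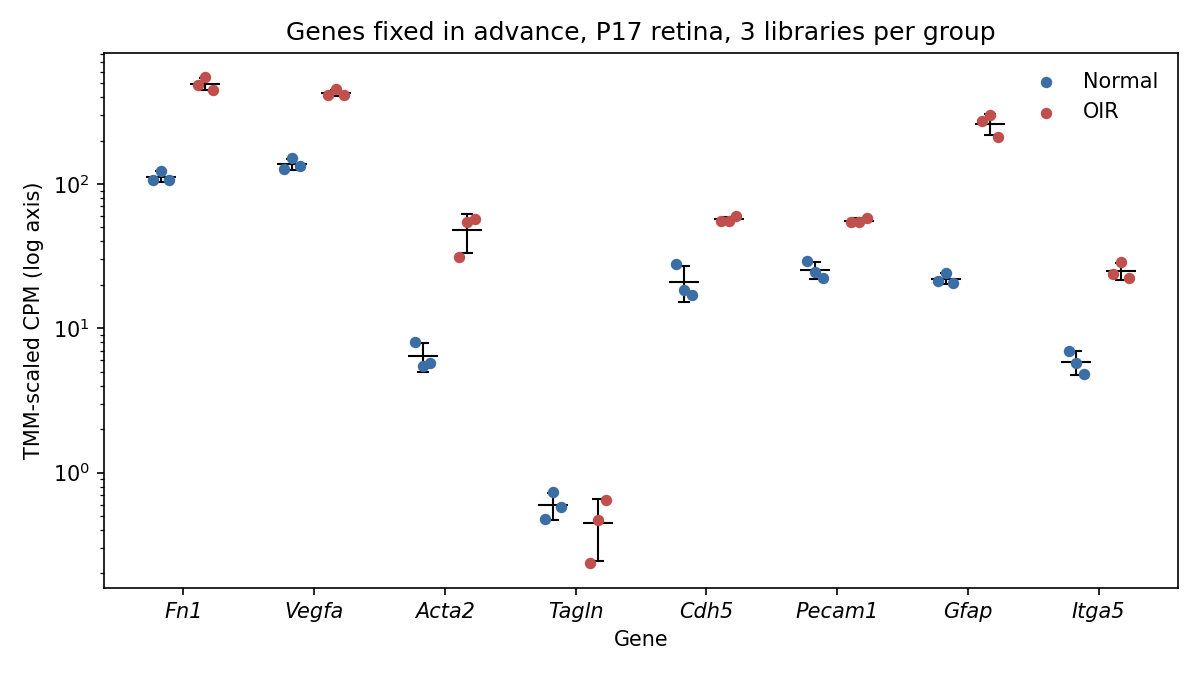
TMM-scaled CPM (log axis) of the 8 genes fixed in advance, with 1 point per library, and the mean and SD of each group of 3 as a bar with whiskers. Every OIR library lies above every normal library for each gene apart from Tagln, for which 29 counts in normal and 23 in OIR retina were found.

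In all, 1901 genes were higher and 1493 lower in OIR retina in edgeR's quasi-likelihood test at an adjusted p under 0.05, which is 19.8% of the genes tested. The rises were larger than the falls: the median log2 change was 0.89 among higher genes and −0.42 among lower genes, and of the 970 genes that changed at least 2-fold, 854 were higher and 116 lower. Of the 3394 changed genes, 3368 had groups that did not overlap. Over all genes tested that share was 36.8%, against 10% by chance for 3 against 3. Without Normal 3 the counts fell to 1237 higher and 769 lower genes, and without OIR 1 or OIR 2 to 761 and 860 lower genes. At an adjusted p under 0.01 they were 1116 higher and 647 lower.

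Among the largest rises were genes of secreted peptides, a receptor and a transcription factor. Edn2, which encodes the vasoconstrictor peptide endothelin 2, rose from 0.291 ± 0.165 to 44.3 ± 15.5 CPM (SD, n = 3), or 150.3-fold. Esm1, a proteoglycan of sprouting endothelial tip cells, rose from 0.186 ± 0.109 to 21.6 ± 7.09 CPM, or 112-fold. Adm, the vasodilator peptide adrenomedullin, rose 44.5-fold, the epithelial anchoring-filament gene Lad1 42.7-fold, the transcription factor gene Egr2 35.5-fold and the urokinase receptor gene Plaur 29.3-fold, with edgeR adjusted p between 1.82e-07 and 4.97e-05. The monocyte chemokine gene Ccl2 had 1 count in the normal libraries and 105 in the OIR libraries, a ratio of 100.3 with a 95% counting interval of 17.6 to 4000. The matrilin gene Matn4 had 2 and 129 counts, a ratio of 61.6 with an interval of 16.7 to 514. These intervals cover counting error only.

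The largest falls were smaller. Gpr101, an orphan G protein-coupled receptor gene, was 11.7-fold lower in OIR retina, with 2.15 ± 0.772 CPM in normal and 0.176 ± 0.102 CPM in OIR libraries (SD, n = 3). BC055402 was 9.78-fold lower, from 14.3 ± 1.15 to 1.45 ± 0.380 CPM. Crispld1 was 6.84-fold lower, the cytokine receptor gene Il20ra 4.75-fold and the paraoxonase gene Pon1 4.63-fold. The ATP-gated channel gene P2rx2 and the sodium channel gene Scn11a were 4.47-fold and 4.39-fold lower. The edgeR adjusted p of the genes named here lay between 2.28e-06 and 0.00602.

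Of the 29 gene lists with enough tested genes, 15 were higher and 8 lower in OIR retina by camera with a preset correlation of 0.01 between genes. With correlations estimated from the data, 2 calls held, those of the endothelial-to-mesenchymal transition genes and the immediate early genes. Their estimated correlations were −0.0158 and 0.0379, against 0.332 for the tip-cell genes and 0.288 for the reactive glia genes. The tip-cell and reactive glia lists had larger median changes, so a held call does not mark the largest change. With estimated correlations camera also uses the few residual degrees of freedom of the 6 libraries, so a lost call does not by itself show correlated genes. The fibronectin receptors had an estimated correlation of 0.0115, near the preset value, yet their camera adjusted p went from 6.73e-07 to 0.055. Other splits of the same 6 libraries into 3 and 3 gave up to 13 lists in one direction with the preset correlation. Those splits mix normal and OIR libraries unevenly and so keep part of the OIR difference, and they do not show how many list calls are false. The counts of members that passed in the edgeR test are given for each list, over all genes tested and adjusted over the list alone.

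**Figure D2:**
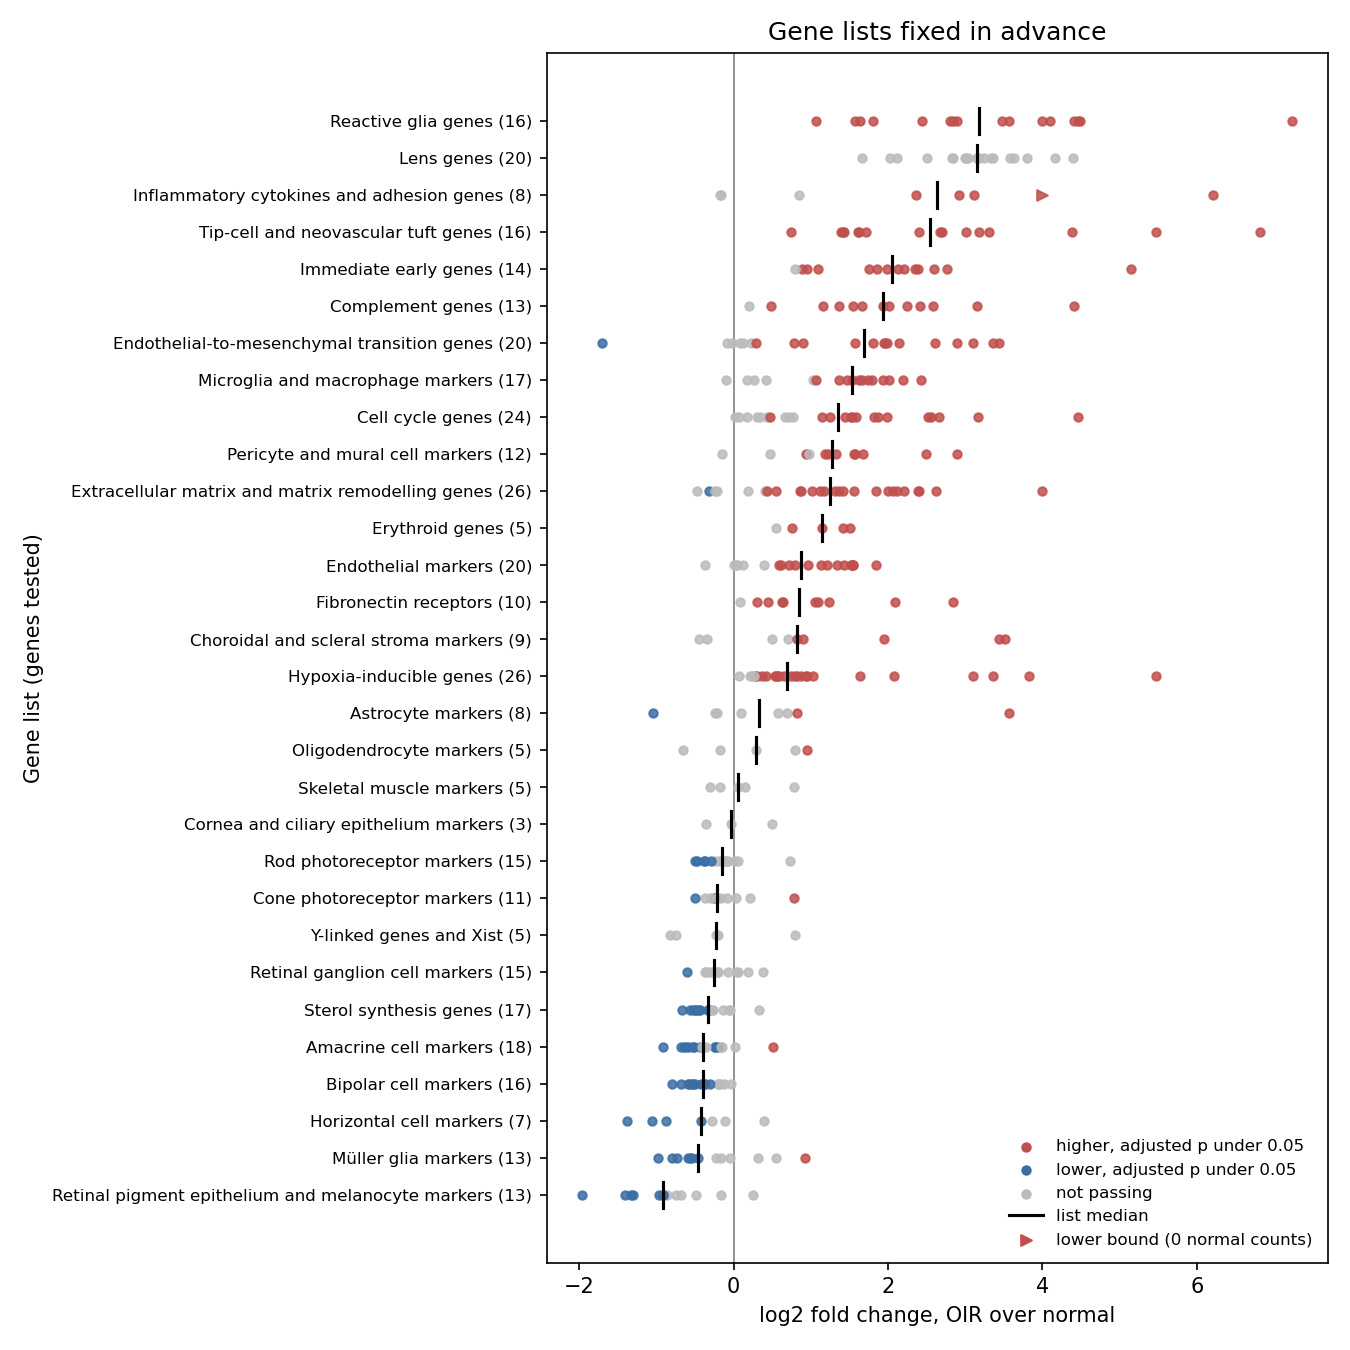
Log2 fold change (OIR over normal) of every tested member of the 30 gene lists, 1 point per gene, with a black bar at each list's median and the number of tested genes in brackets. Red and blue points passed an adjusted p of 0.05 in edgeR's test and grey points did not, and Ccl3, with 0 normal counts, is drawn at its lower bound. All 16 tip-cell genes and all 16 reactive glia genes are red, and all 20 lens genes are grey.

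Of 26 hypoxia-inducible genes tested, 22 rose and none fell, or 24 when adjusted over the list alone, with a median log2 change of 0.69. Camera gave the list an adjusted p of 1.11e-14, and the adjusted p was 0.0797 with an estimated correlation. Besides Vegfa and Adm, Egln3, a prolyl hydroxylase that marks HIF proteins for degradation, rose 8.57-fold from 4.61 ± 1.05 to 39.7 ± 5.90 CPM (SD, n = 3), and Bnip3, a mitophagy gene, rose 2.04-fold from 97.6 ± 3.43 to 199.3 ± 16.6 CPM. The genes of endothelial tip cells and neovascular tufts rose without exception, 16 of 16 in both counts, with a median log2 change of 2.54. Among them the vascular peptide gene Apln rose 20.8-fold from 8.98 ± 2.81 to 187.7 ± 32.5 CPM, Igfbp3 9.90-fold and the sialomucin gene Cd34 3.07-fold. This list had a camera adjusted p of 1.76e-15, and an adjusted p of 0.0797 with an estimated correlation.

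Among the endothelial-to-mesenchymal transition genes, 14 of 20 tested rose and 1 fell, or 15 and 1 when adjusted over the list alone, with a median log2 change of 1.69. In camera the adjusted p was 9.87e-09, and the adjusted p was 0.0436 with an estimated correlation. Besides Fn1, the intermediate filament gene Vim rose 2.97-fold from 217 ± 1.56 to 644 ± 8.13 CPM (SD, n = 3), the matricellular gene Ctgf 6.12-fold from 13.8 ± 0.980 to 84.4 ± 20.7 CPM and the fibrillar collagen gene Col3a1 3.86-fold from 7.77 ± 0.983 to 30.0 ± 2.07 CPM. The member that fell was Fap, a fibroblast protease gene, with a log2 change of −1.71 (edgeR adjusted p of 0.00507). The transcription factor genes Snai1 and Snai2 rose by 1.81 and 1.98 on the log2 scale (edgeR adjusted p of 0.0144 and 0.014). Both were low, going from 0.528 ± 0.266 to 1.88 ± 0.637 CPM and from 0.287 ± 0.152 to 1.16 ± 0.280 CPM. The mesenchymal cadherin gene Cdh2 and the transcription factor genes Zeb1 and Zeb2 did not pass, with log2 changes of 0.22, 0.08 and −0.09, and Twist1 was not tested. Cdh2 passed with library totals alone (0.27, adjusted p of 0.0343) and without OIR 2 (0.29, adjusted p of 0.0357). Over the same libraries the median log2 change was 0.88 for endothelial markers and 1.28 for mural cell markers.

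Extracellular matrix and matrix remodelling genes rose in 20 of 26 cases and fell in 1, or 21 and 2 when adjusted over the list alone, with a median log2 change of 1.24. The basement membrane collagen genes Col4a1 and Col4a2 rose 6.16-fold, from 117 ± 16.5 to 719 ± 73.6 CPM, and 4.63-fold, from 97.8 ± 12.4 to 453 ± 57.2 CPM (SD, n = 3). The collagen cross-linking enzyme gene Loxl2 rose 5.23-fold and the laminin gene Lama4 4.01-fold. The single fall was in the fibrillin gene Fbn1, with a log2 change of −0.32, which no longer passed in 6 of the alternatives run, among them those without Normal 1 (−0.25), Normal 3 (−0.33), OIR 2 (−0.32) and OIR 3 (−0.26), while 3 members fell without Normal 2. The camera adjusted p of the list was 8.38e-12, and the adjusted p was 0.098 with an estimated correlation. Of the fibronectin receptor genes, 9 of 10 rose, also when adjusted over the list alone, and none fell. Besides Itga5, the integrin gene Itgb1 rose 2.13-fold from 97.7 ± 5.95 to 207.9 ± 12.2 CPM, Itgb3 7.19-fold from 1.00 ± 0.145 to 7.27 ± 2.15 CPM and the syndecan gene Sdc4 1.54-fold. This list had a camera adjusted p of 6.73e-07, and an adjusted p of 0.055 with an estimated correlation.

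Endothelial markers rose in 14 of 20 cases and none fell over all genes tested, with 14 higher and 1 lower when adjusted over the list alone. Vwf, the von Willebrand factor gene, rose 3.59-fold from 26.6 ± 2.48 to 95.6 ± 10.6 CPM (SD, n = 3), the TGF-beta co-receptor gene Eng 2.92-fold and the guidance receptor gene Robo4 2.89-fold. The VEGF receptor gene Kdr had a log2 change of 0.01, which turned to −0.03 without Normal 2, −0.04 without OIR 1 and −0.03 without OIR 3, and the angiopoietin receptor gene Tek one of −0.37, and neither passed. Camera gave the list an adjusted p of 4.43e-08, and the adjusted p was 0.152 with an estimated correlation. Pericyte and mural cell markers rose in 9 of 12 cases, or 10 when adjusted over the list alone, and none fell. Besides Acta2, the Notch receptor gene Notch3 rose 2.97-fold, the G protein regulator gene Rgs5 2.51-fold from 189.5 ± 12.7 to 476 ± 34.4 CPM and the PDGF receptor gene Pdgfrb 2.27-fold. In camera the adjusted p was 2.3e-08, and the adjusted p was 0.113 with an estimated correlation. Erythroid genes, a measure of blood in the tissue, rose in 4 of 5 cases in both counts, with Hbb-bs 2.83-fold and Hba-a1 2.66-fold higher, Hba-a2 2.22-fold and Hbb-bt 1.68-fold. Hbb-bt no longer passed without Normal 2 (log2 change 0.59), Normal 3 (0.78), OIR 2 (0.71) or OIR 3 (0.65), and reads of these globin copies cannot be cleanly separated. The list had a camera adjusted p of 0.000465, and an adjusted p of 0.155 with an estimated correlation.

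Reactive glia genes rose in 16 of 16 cases in both counts, with a median log2 change of 3.18. Besides Gfap and Vim, the complement gene C4b rose 21.2-fold from 1.79 ± 0.606 to 38.0 ± 3.52 CPM and the protease inhibitor gene A2m 7.43-fold from 10.4 ± 1.14 to 77.1 ± 13.4 CPM (SD, n = 3). C4b shares reads with a near-identical copy and its level is uncertain. The camera adjusted p was 8.67e-16, and the adjusted p was 0.0797 with an estimated correlation. Markers of Müller glia, the main glial cell of the retina, moved the other way: 7 of 13 fell and 1 rose, or 8 and 3 when adjusted over the list alone. The lipid transporter gene Abca8a fell by 0.99 on the log2 scale from 245 ± 17.6 to 124 ± 18.7 CPM, the potassium channel gene Kcnj10 fell by 0.80 and the water channel gene Aqp4 fell by 0.73. The transcription factor gene Sox9 rose 1.90-fold from 27.8 ± 2.30 to 52.9 ± 4.66 CPM, and without Normal 1 a further member rose. Camera gave the list an adjusted p of 0.00799, and the adjusted p was 0.365 with an estimated correlation. Of 8 astrocyte markers, 2 rose, Gfap and the PDGF receptor gene Pdgfra (1.76-fold), and the zinc transporter gene Slc39a12 fell by 1.04 on the log2 scale, in both counts. Slc39a12 no longer passed without Normal 3 (−0.85), and the list was not called by camera (adjusted p of 0.291, and adjusted p of 0.39 with an estimated correlation).

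Microglia and macrophage markers rose in 12 of 17 cases, or 13 when adjusted over the list alone, and none fell. The complement subunit genes C1qa, C1qb and C1qc rose 4.03-fold, 3.17-fold and 3.84-fold, and the macrophage mannose receptor gene Mrc1 rose 5.37-fold from 1.00 ± 0.342 to 5.43 ± 0.728 CPM (SD, n = 3). In camera the adjusted p was 3.51e-08, and the adjusted p was 0.111 with an estimated correlation. Of 8 tested inflammatory cytokine and adhesion genes, 5 rose in both counts and none fell, with a median log2 change of 2.64 that was the same with Ccl3 at its bound. The filter on low counts was run anew in each fit, so the members tested can differ from these 8. Without Normal 1, 8 members rose with a median of 4.22, and with the stricter filter on low counts, which removed chemokine genes, 2 rose with a median of 0.845. Besides Ccl2, the TWEAK receptor gene Tnfrsf12a rose 7.54-fold and the leukocyte adhesion gene Icam1 5.13-fold, and the chemokine gene Ccl3, with 0 normal and 50 OIR counts, was at least 15.9-fold higher against a floor of 3 counts over the group. This list had a camera adjusted p of 0.00148, an adjusted p of 0.155 with an estimated correlation, and a camera adjusted p of 0.133 with the stricter filter. Complement genes, which share C4b and the C1q genes with the lists above, rose in 12 of 13 cases in both counts, with Serping1, the C1 inhibitor gene, 4.76-fold higher. Their camera adjusted p was 9.48e-10, and the adjusted p was 0.055 with an estimated correlation.

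Cell cycle genes rose in 15 of 24 cases, or 18 when adjusted over the list alone, and none fell, with 9 higher without Normal 3 and 9 without OIR 1. The proliferation marker Mki67 rose 22.1-fold from 0.433 ± 0.117 to 9.68 ± 4.11 CPM (SD, n = 3), the topoisomerase gene Top2a 8.93-fold, the mitotic kinase gene Cdk1 5.86-fold and the replication helicase gene Mcm6 2.22-fold. Camera gave the list an adjusted p of 9.48e-10, and the adjusted p was 0.0797 with an estimated correlation. Immediate early genes, which respond within minutes to stimulation and also to tissue handling, rose in 13 of 14 cases in both counts, and Arc was the member that did not pass (log2 change 0.79). Besides Egr2, Fos rose 4.61-fold from 16.9 ± 0.812 to 77.6 ± 12.1 CPM, Junb 6.79-fold, Fosl2 5.11-fold and the nuclear receptor gene Nr4a1 3.62-fold. In camera the adjusted p was 1.09e-12, and the adjusted p was 0.0436 with an estimated correlation.

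Markers of several retinal neurons were lower. Bipolar cell markers fell in 11 of 16 cases, or 13 when adjusted over the list alone, and none rose. The ON-bipolar glutamate receptor gene Grm6 fell by 0.59 on the log2 scale from 221 ± 8.60 to 146 ± 4.18 CPM, the calcium-binding protein gene Scgn fell by 0.80, the channel gene Trpm1 fell by 0.58 and Gpr179 fell by 0.54 (SD, n = 3). The camera adjusted p was 4.43e-08, and the adjusted p was 0.098 with an estimated correlation. Amacrine cell markers fell in 11 of 18 cases and rose in 1, or 13 and 1 when adjusted over the list alone, with 7 lower without Normal 3 and 7 without OIR 1. The glycine transporter gene Slc6a9 fell by 0.68, the GABA-synthesis gene Gad1 fell by 0.65 from 354 ± 21.0 to 226 ± 17.8 CPM and the transcription factor gene Tfap2b fell by 0.44. The member that rose was the neuropeptide gene Npy (log2 change 0.51), which no longer passed without Normal 3 (0.41), OIR 1 (0.45) or OIR 3 (0.49). Camera gave the list an adjusted p of 2.13e-06, and the adjusted p was 0.113 with an estimated correlation. Horizontal cell markers fell in 4 of 7 cases in both counts: the gap junction gene Gja10 fell by 1.38, the calcium-binding protein gene Calb1 fell by 1.06 from 137 ± 10.3 to 66.0 ± 11.4 CPM, Lhx1 fell by 0.87 and Prox1 fell by 0.43, and without Normal 1 a further member rose. In camera the adjusted p was 0.0053, and the adjusted p was 0.108 with an estimated correlation.

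Rod photoreceptor markers fell in 5 of 15 cases and none rose over all genes tested, with 5 lower and 1 higher when adjusted over the list alone and 1 higher without Normal 2. The phototransduction genes Sag, Gnat1, Pde6b and Pde6a fell by 0.51, fell by 0.47, fell by 0.38 and fell by 0.37 on the log2 scale, with Gnat1 at 9705 ± 431 CPM in normal and 6991 ± 391 CPM in OIR retina (SD, n = 3). The camera adjusted p was 0.00192, and the adjusted p was 0.266 with an estimated correlation. Of 11 cone markers, Cngb3 and Gnat2 fell by 0.50 and fell by 0.24 and Gnb3, which bipolar cells also express, rose 1.71-fold from 262 ± 14.8 to 449 ± 68.2 CPM, and adjusted over the list alone 3 fell and 1 rose. Cngb3 no longer passed without Normal 2 (−0.38), Normal 3 (−0.52), OIR 1 (−0.47) or OIR 3 (−0.50), nor Gnat2 without Normal 3 (−0.24), OIR 1 (−0.20), OIR 2 (−0.28) or OIR 3 (−0.25) or with library totals alone (−0.19), whereas 4 cone markers fell without Normal 1. The cone list was not called by camera (adjusted p of 0.0902, and adjusted p of 0.54 with an estimated correlation), except without OIR 2 (adjusted p of 0.0253). Of 15 ganglion cell markers 1 passed in both counts, the heavy neurofilament gene Nefh, which fell by 0.60. The more abundant Nefl, Nefm and Thy1 had log2 changes of −0.38, −0.35 and −0.26 and did not pass, but passed without Normal 2 (−0.54, −0.50 and −0.43), where 7 members fell, against 2 without OIR 3; without Normal 1, 1 member rose. The ganglion cell list had a camera adjusted p of 0.0462, lost without Normal 1 (0.431), Normal 3 (0.0997), OIR 1 (0.103) or OIR 2 (0.0721), and an adjusted p of 0.64 with an estimated correlation. Sterol synthesis genes fell in 10 of 17 cases, or 13 when adjusted over the list alone, and none rose, but 3 fell without Normal 3 and 3 without OIR 1. The sterol sensor gene Insig1 fell by 0.52 and the mevalonate pathway gene Hmgcs1 fell by 0.44. Hmgcs1 no longer passed without Normal 3 (−0.39). Camera gave the list an adjusted p of 3.99e-05, and the adjusted p was 0.323 with an estimated correlation.

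Genes of tissues next to the retina differed between libraries. Retinal pigment epithelium and melanocyte markers fell in 7 of 13 cases, or 9 when adjusted over the list alone, and none rose. The visual-cycle genes Lrat, Rgr and Rdh5 fell by 1.96, fell by 1.41 and fell by 1.33 on the log2 scale, with Rgr at 80.2 ± 18.8 CPM in normal and 30.2 ± 3.18 CPM in OIR retina (SD, n = 3), and the transthyretin gene Ttr fell by 0.97. Summed over the list, the normal libraries held 495, 280.2 and 359 CPM and the OIR libraries 171, 212 and 168 CPM. In camera the adjusted p was 3.99e-05, and the adjusted p was 0.259 with an estimated correlation. None of 20 lens genes passed in either count, with a median log2 change of 3.15, a camera adjusted p of 0.0623 and an adjusted p of 0.694 with an estimated correlation. Their sum was 45.6, 563 and 626 CPM in the normal libraries and 156, 586 and 8967 CPM in OIR 1, OIR 2 and OIR 3, and without OIR 3 the median log2 change was −0.20. Cryaa, Cryab, Cryba1 and Crybb2, the most abundant of them, had log2 changes of 3.03, 2.11, 3.18 and 3.36 with standard errors of 1.45, 0.79, 1.39 and 1.34, and without OIR 3 Cryaa and Cryba1 had changes of −0.14 and −0.28. The list was called higher by camera without Normal 2 (adjusted p of 0.0325), Normal 3 (0.0131), OIR 1 (0.00045) or OIR 2 (0.0332), and without OIR 1, where 9 members passed, Cryab was among them (2.60). Without a filter on low counts the list was also called (adjusted p of 0.0195), with 21 members higher, among them Cryaa, Cryab, Cryba1 and Crybb2.

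**Figure D3:**
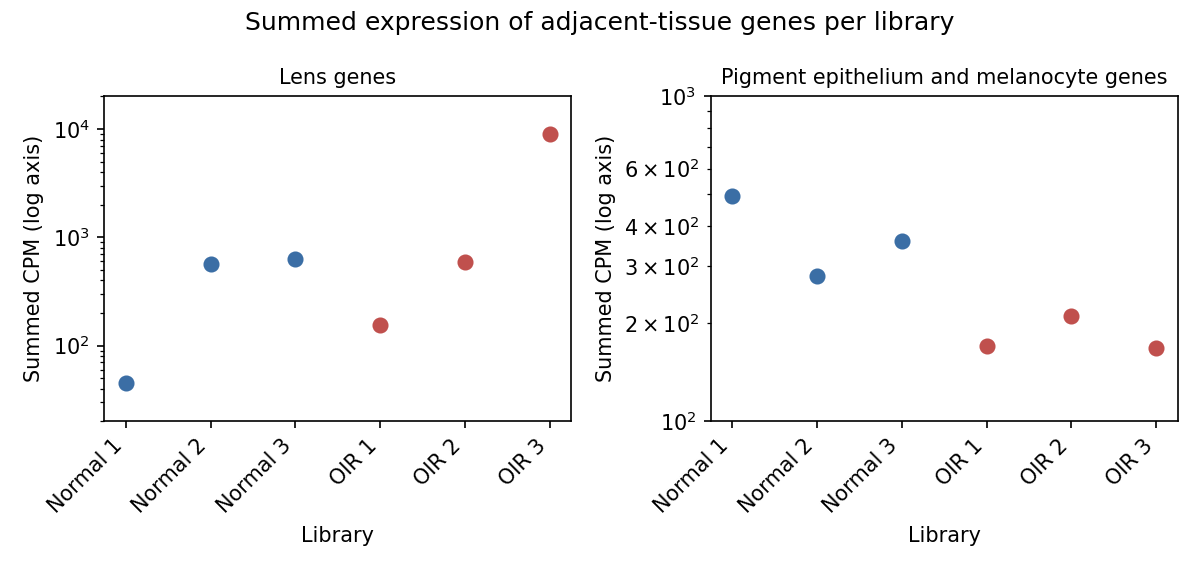
Summed CPM (log axes) of the lens genes and of the pigment epithelium and melanocyte genes, 1 point per library, with normal libraries in blue and OIR libraries in red. OIR 3 stands apart at 8967 CPM of lens genes, and the 3 OIR libraries hold 168 to 212 CPM of pigment epithelium genes against 280.2 to 495 CPM in the normal libraries.

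Choroidal and scleral stroma markers rose in 5 of 9 cases in both counts and none fell, with Col6a3 11.4-fold higher, from 1.502 ± 0.635 to 17.3 ± 5.62 CPM, and Col1a1 10.9-fold higher, from 2.04 ± 0.268 to 22.2 ± 6.60 CPM (SD, n = 3). The 5 were Col1a1, Col1a2, Col3a1, Pdgfra and Col6a3. No tested member among Dcn, Lum, Fmod, Ogn, Omd and Thbs4 passed, and the lowest log2 change in the list was −0.45. This list, which shares Col1a1, Col1a2 and Col3a1 with the endothelial-to-mesenchymal list and Pdgfra with the astrocyte list, had a camera adjusted p of 0.00257, and an adjusted p of 0.111 with an estimated correlation. Of 5 oligodendrocyte markers, Cnp rose 1.94-fold, while Mbp and Ermn had log2 changes of −0.17 and −0.66 and did not pass, and adjusted over the list alone 2 rose and 1 fell. Ermn passed without Normal 1 (−0.81), and 2 members rose without Normal 2 and 2 without OIR 1. No member passed in either count among 5 skeletal muscle genes, where Pvalb, Acta1, Mylpf and Ckm had log2 changes of −0.31, −0.18, 0.06 and 0.78, nor among 3 corneal and ciliary epithelium genes, where Aldh1a3, Wfdc2 and Wif1 had changes of 0.49, −0.04 and −0.35. Aldh3a1 was not tested, with 22 counts in normal and 23 in OIR libraries. Camera called neither the oligodendrocyte list (adjusted p of 0.733, and adjusted p of 0.748 with an estimated correlation) nor the muscle list (0.779, and adjusted p of 0.789 with an estimated correlation). None of the 5 sex-linked genes passed: Xist, Ddx3y, Eif2s3y and Kdm5d had log2 changes of 0.79, −0.23, −0.21 and −0.83, with 2 male libraries among the normal and 1 among the OIR libraries, and the list was not called (adjusted p of 0.526, and adjusted p of 0.694 with an estimated correlation). Without Normal 2, the female normal library, Xist passed (10.8), and without OIR 2, the male OIR library, Ddx3y, Eif2s3y and Kdm5d passed (−11.9, −11.6 and −9.48). With sex as a covariate the sign of Ddx3y and Eif2s3y turned and both passed (0.77 and 0.79). That covariate was read from these same genes, and the female libraries held 0 counts of both. These 2 calls therefore rest on 1 male OIR library, OIR 2.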

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

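The fits with sex as a covariate and without lens genes were chosen after seeing the data, and the other alternatives before. Fn1 stayed higher in all 15 alternatives, with log2 changes of 2.05 to 2.21 and adjusted p of 9.49e-106 to 4.66e-05. With each library left out in turn, 1237 to 2097 genes were higher, 761 to 1734 lower and 781 to 1056 changed at least 2-fold, with fewer samples in each such fit. An adjusted p under 0.01 left 1116 higher and 647 lower genes. With an estimated correlation between genes 2 lists were higher and 0 lower. Fry, which does not compare a list with the other genes, called 16 lists higher and 7 lower. DESeq2 kept 95.2% of the calls in the same direction, limma-voom 96.8%, library totals alone 90.1%, sex as a covariate 76.1%, with 1612 higher and 1049 lower genes, and the fit without lens genes 99.4%. Without a filter the prior degrees of freedom rose from 6.64 to 129 as 30543 genes entered, which makes p-values smaller (Fn1 6.11e-50). The replicate block gave 1680 higher and 1166 lower genes. Deviations of libraries with the same number correlated at 0.061, −0.164 and 0.074, and no normal library correlated best with the OIR library of its own number. The titles do not say that the numbers pair samples, and the main test without a block was fixed beforehand. Under the block Gnat2 no longer passed and the lens list was called higher (adjusted p of 2.1e-05). The ganglion cell list was not called with the stricter filter (adjusted p of 0.0516), the sex covariate (0.182) or fry (0.379), the astrocyte list was called by fry (0.000769), and Nefl and Nefm passed with DESeq2 (adjusted p of 0.0124 and 0.0224). Of 123 other genes named by rule, 102 kept direction and side of the threshold in every alternative run.

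The signs that turned belonged to genes that did not pass with all 6 libraries and no covariate, and the cause was not tested beyond the library left out. Without OIR 3, Cryaa was at −0.14, Cryba1 at −0.28 and Mylpf at −0.00010, and without Normal 2 Mylpf was at −0.12. The highest values with a library left out were 3.61 for Cryaa, without Normal 2, and 3.86 for Cryba1, without Normal 3. Wfdc2 was at 0.0796 with limma-voom, 0.0067 with library totals alone, 0.037 with the replicate block, 0.48 without Normal 1, 0.049 without OIR 1, −0.32 without Normal 2 and 0.19 with the sex covariate. Kdr was at −0.00074 with DESeq2, −0.00075 with median-of-ratios scaling, −0.015 with the sex covariate, −0.031 without Normal 2, −0.044 without OIR 1, −0.032 without OIR 3 and 0.065 without OIR 2. Ddx3y and Eif2s3y were at 0.41 and 0.47 without Normal 3, 0.35 and 0.37 without OIR 1 and 0.35 and 0.37 without OIR 3, with −11.93 and −11.60 without OIR 2. With the sex covariate Xist was at −0.20 and Kdm5d at 0.18, and Ddx3y and Eif2s3y passed as higher, at 0.77 and 0.79 (adjusted p of 0.0233 and 0.0333). Sex was read from these same genes, and OIR 2 was the only OIR library with counts of Ddx3y and Eif2s3y. Tagln was tested only without a filter (−0.40, adjusted p of 0.732), at 4 to 12 counts per library, and the size of change that could be found at such counts was not measured.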

Other observations

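The 7 gene lists of the first 2 paragraphs and all tests below, apart from the splits of the samples, were chosen after the results were seen. The camera p-values of these lists were adjusted over the 7 lists alone. Genes of interferon signalling and antigen presentation rose in 11 of 17 cases in OIR retina and none fell (14 when adjusted over the list alone; camera adjusted p of 1.33e-07, and adjusted p of 0.228 with an estimated correlation). The interferon regulator Irf7 rose from 8.16 ± 1.11 to 25.9 ± 2.20 CPM (SD, n = 3), the antiviral membrane protein gene Ifitm3 from 5.35 ± 1.25 to 20.2 ± 2.58 CPM, the MHC class I gene H2-K1 from 15.5 ± 1.65 to 44.4 ± 4.47 CPM and its light chain gene B2m from 22.2 ± 4.33 to 44.8 ± 2.51 CPM. Of 11 tested cell death genes 6 rose and 1 fell, in both counts (adjusted p of 0.00194, and adjusted p of 0.17 with an estimated correlation). The necroptosis kinase gene Ripk3 had 3 normal and 92 OIR counts, a ratio of 29.3 with a 95% counting interval of 9.72 to 145, and its effector gene Mlkl rose by 2.14 on the log2 scale. The TNF receptor gene Tnfrsf1a rose by 1.73 and Casp8 by 1.31. Of 11 oxidative stress and metallothionein genes 5 rose and none fell in both counts, with a median log2 change of 0.22 (camera adjusted p of 0.00427, and adjusted p of 0.185 with an estimated correlation). The haem-degrading enzyme gene Hmox1 went from 2.85 ± 0.377 to 65.7 ± 33.3 CPM. The metallothionein genes Mt1 and Mt2 rose by 1.99 and 2.74, Osgin1 by 1.26 and Txnrd1 by 0.31. The other 6, Nqo1, Gclc, Gclm, Gsr, Srxn1 and Slc7a11, did not pass, with log2 changes of −0.29 to 0.22. Txnrd1 no longer passed without Normal 2 (0.26), OIR 1 (0.30) or OIR 2 (0.27).

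Among 12 genes of the blood-retina barrier the members split, with 2 higher and 3 lower, or 3 and 3 when adjusted over the list alone (adjusted p of 0.158, and adjusted p of 0.589 with an estimated correlation). The barrier transporter genes Slco1a4, Slco1c1 and Slc22a8 fell by 1.62, fell by 1.45 and fell by 1.27 on the log2 scale, from 31.0 ± 3.36 to 10.1 ± 3.16 CPM, from 15.83 ± 0.638 to 5.78 ± 2.61 CPM and from 11.9 ± 2.31 to 4.92 ± 0.0717 CPM (SD, n = 3), while most endothelial markers rose. The tight junction gene Cldn5 rose by 0.61 and the efflux pump gene Abcg2 by 0.47. Cldn5 no longer passed without Normal 2 (0.62), Normal 3 (0.44), OIR 1 (0.53) or OIR 3 (0.52), nor Abcg2 without Normal 3 (0.47), OIR 1 (0.38) or OIR 3 (0.43). The lipid transporter gene Mfsd2a did not pass, at −0.42. Synaptic genes fell in 8 of 16 cases and none rose, or 10 lower and 1 higher when adjusted over the list alone (adjusted p of 0.00194, and adjusted p of 0.17 with an estimated correlation), with Syn2 at −0.69, Cplx3 at −0.50, Bsn at −0.48 and Snap25 at −0.37. Of 10 genes of Norrin and Wnt signalling 2 rose in both counts, Fzd4 by 0.55 and Lrp5 by 0.60 (camera adjusted p of 0.0498, and adjusted p of 0.44 with an estimated correlation). That share lies near the 19.8% of all genes tested that changed. Of 12 genes of the integrated stress and unfolded protein responses 4 rose, or 4 with 1 fall when adjusted over the list alone, among them Trib3 by 0.87, Ddit3 by 0.38 and Atf4 by 0.31, while the chaperone gene Hspa5 did not pass, at −0.06. Atf4 no longer passed without Normal 3 (0.25) or OIR 2 (0.25), and the list was not called (adjusted p of 0.384, and adjusted p of 0.599 with an estimated correlation).

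Fn1 and the endothelial-to-mesenchymal genes rose together with endothelial and mural markers, so a change in cell shares may account for part of the rise. None of the 20 endothelial markers rose more than Fn1. Against their mean, Fn1 rose by a further 1.28 on the log2 scale (pooled SD 0.189). This argues against a larger endothelial share as the whole source of the Fn1 rise. The list's mean rose by a further 0.48 (pooled SD 0.092) against the same markers. These markers ranged from −0.37 to 1.85 around a mean of 0.85, and the list's mean change of 1.37 lies inside that range. The gap therefore does not decide the question for the list. With Acta2, which both lists hold, left out of each, the mean of 19 list genes moved by 0.07 against that of 11 mural markers (pooled SD 0.0856), as a larger mural share would give. Against all 12 mural markers Fn1 moved by 0.814 (pooled SD 0.167), and Acta2 and Des rose more than Fn1. More mural cells, tip and tuft endothelial cells, fibroblasts or macrophages, higher expression within them or in glia, and a change of endothelial cells themselves all stay open, since whole retina does not show which cells hold the transcripts.

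The fall of pigment epithelium genes may reflect less of that tissue carried over with the retina. The 4 visual-cycle genes (Rpe65, Lrat, Rdh5, Rgr) changed on average by −1.47 on the log2 scale (pooled SD 0.325) and the 6 pigment genes (Pmel, Dct, Tyr, Tyrp1, Mlana, Slc45a2) by −0.699 (pooled SD 0.402). The gap between them moved by −0.774 (pooled SD 0.149), more than carry-over of a single tissue would give, but choroidal melanocytes also express the pigment genes, so carry-over and lower visual-cycle expression cannot be told apart. Müller glia are known to express Rgr, and a change within the retina was not tested.

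The lens genes were highest in OIR 3 for 20 of 20 tested genes, and without that library their median log2 change was −0.20 (−0.199), with the sums of OIR 1 and OIR 2 inside the range of the normal libraries. This is consistent with lens tissue carried over in OIR 3, where the sum was 8967 CPM and Cryaa the most abundant member, and argues against induction of crystallins by the OIR treatment at the size seen over all libraries. Without OIR 3, 1537 genes were higher and 1255 lower.

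The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits cannot fall under 0.1, too few to exclude chance. The real split gave 1901 higher and 1493 lower genes and 970 changed at least 2-fold, each reached by 1 of the 10 splits, the real one, and the highest of the others were 4 genes in one direction and 5 changed at least 2-fold. For gene lists the real split gave 15 higher, reached by 1 of the 10, and 8 lower, reached in one direction by 8 of the 10, with 13 as the highest other. Every other split mixes normal and OIR libraries unevenly. It thus keeps part of the OIR difference between its groups, which lists can pick up, and puts the rest within them, which lowers gene calls. The splits therefore show neither how many genes nor how many lists chance would give.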
